A study of Caulobacter vibrioides NA1000 with 8 samples.

How the data were processed

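The series holds RNA-seq and transposon insertion sequencing (Tn-seq) of *Caulobacter vibrioides* NA1000, a laboratory strain of a freshwater bacterium with an asymmetric cell cycle. Per the labels, wild-type cells and cells with the *lon* gene deleted were grown exponentially in PYE, a peptone and yeast extract medium, with no further treatment. The 4 RNA-seq samples, 2 per genotype, were analysed. The 4 Tn-seq samples were not analysed here.

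The authors deposited 1 table of raw read counts per gene, with 1 column per RNA-seq sample and 4084 genes. Per the labels' protocols, ribosomal RNA was depleted with Ribo-Zero before standard Illumina library preparation. BWA, SAMtools, bedtools and edgeR were named without versions, per the submitters' processing notes. The genome build, the annotation, the strand setting and the treatment of reads with several matches were not given in the sources used here. Counts of overlapping genes and of antisense neighbours are therefore uncertain, as are those of the near-identical rRNA copies. Among named genes, *terB*, *hdaA*, *grpE*, *nuoA*, *cspD* and CCNA_02862 overlap a neighbour, as do *nuoB*, *hfaD*, *sdhC* and *trwB*, which the naming rule also takes. Library totals ranged from 28120941 to 34134120 counts, and the lowest count of any gene in any library was 92. The relative variance from counting, at a gene's mean count, exceeded edgeR's common dispersion of 0.00834 for 1 of the 4084 genes. Ribosomal RNA still took 29.6% to 34.3% of the counts, and its genes were kept as ordinary rows.

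Columns were matched to samples by the replicate and genotype in their names and the sample titles. All 4084 gene identifiers matched the locus tags of the RefSeq gene table of assembly ASM2200v1, which supplied symbols for 671 genes, neighbours, gene lengths and overlaps. Since the authors' build is not stated, no coordinates are given, and lengths served only for read densities and the floor described below. 13 genes of the reference table were not rows of the deposited table.

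The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 139.5 between the wild-type libraries and 78.5 between the *lon*-deletion libraries. Spearman's rho between replicates, across genes that are not independent replicates, was 0.986 and 0.992.

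The following choices were fixed before the data were examined, unless stated otherwise. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, genotype as the only term). The filter removed 0 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes and called at 0.05. *lon* was left out of counts of changed genes. Standard errors were derived from the fold change and the quasi-likelihood F. Expression is given as TMM-scaled CPM, mean ± SD of 2 libraries, and read density as reads per kb of gene on the same scale (RPKM).

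30 gene lists were fixed before the data were seen. They were matched here by symbol, and the capsule list by a range of locus tags. Single locus tags that the plan also named were not used. 22 lists had at least 5 measured genes and were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 22. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 libraries, so it could hardly pass any list. The reference table gave no product descriptions, so 5 lists resting on products had no identified gene: aminoacyl-tRNA synthetases, TonB-dependent receptors, transporters, mobile elements with prophage, and c-di-GMP with two-component signalling. 3 lists had 1 to 4 genes and were not tested as lists.

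Named genes were taken by rule. They comprised *lon* and its neighbours, and the focal genes *nrdA*, *nrdB*, *ccrM*, *dnaA*, *sciP*, *gcrA*, *ctrA*, *recA*, *lexA*, *dnaK*, *groEL*, *clpB*, *clpP*, *clpX* and *ftsZ*. Of these, *nrdA* and *groEL* were not matched by symbol, so no values are given under these names. The rule added the 10 largest rises and 10 largest falls past the threshold with non-overlapping groups and a mean CPM of at least 5, among genes with a symbol where the rule had asked for a product. It also added the 3 largest rises and falls whatever the name, and up to 4 members of each list by adjusted p. *nrdE* was added by its symbol before its values were seen. *ibpA*, *relE1*, *dnaJ*, *dnaG*, *gmk*, *bapE*, *imuA*, *mutS*, *alkB*, *fljK*, *socA*, *perP*, *dinB*, *dnaE2*, *imuB*, CCNA_00721 and CCNA_00722 were named after their values were seen.

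Distance from the replication origin was measured along the gene order from the first gene of the table, per 1000 genes by the shorter way round, in place of the planned distance in bases. The slope of fold change on it was tested against 4083 circular shifts of the gene order, two-sided.

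After the data were seen, a floor of read density was examined. The floor was the 2nd percentile of reads per kb over protein-coding genes of at least 300 nucleotides in each library. In an added alternative, the floor times gene length was subtracted from each count, and genes with at least 50% of their mean reads left were kept. The mean was taken over all 4 libraries, so a weak gene was kept more readily if it rose than if it fell. The 2965 genes kept were tested with limma-trend on log2 CPM with a prior count of 5. Their lists were tested with camera at the preset and at an estimated correlation. A further added test (edgeR's glmTreat) asked which genes changed by more than the ratio of the floors between genotypes.

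Other alternatives were RLE, upper-quartile and library-total scaling, other low-count filters, the DESeq2 1.42.0 Wald test, edgeR's likelihood-ratio and legacy tests, limma-voom, a replicate block, removal of rRNA and tRNA rows, and leaving out each library in turn.

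The pipeline was tested on simulated data for the comparison of *lon* deletion with wild type, using the 4084 real genes with 200 changed. The edgeR test recovered 86.6% of 67 genes changed 1.5-fold, 98.5% of 67 changed 2-fold and 100% of 66 changed 4-fold. It called 14 of 3884 unchanged genes. When the floors of the real libraries were added to unchanged signal, it called 624 unchanged genes higher and 856 lower. After floor subtraction, 4 unchanged genes were called higher and 3 lower among 2866 kept. Of genes changed 1.5-fold 48.9% were recovered, and 100% of those changed 2-fold or 4-fold. The simulated floor followed gene length and was even along the chromosome, as the subtraction assumes. In the real libraries a low percentile of read density was 1.37 to 1.49 times higher near the origin than on the far side. These few false calls therefore do not show how well the subtraction works on the real floor.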

Results

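RNA from exponentially growing *Caulobacter vibrioides* NA1000 was sequenced in 2 wild-type and 2 *lon*-deletion samples. Lon is an ATP-dependent protease that degrades damaged proteins and several regulators of the cell cycle. The series title frames the comparison as a link between Lon, nucleotide metabolism and proteotoxic stress. The wild-type libraries held 28120941 and 34134120 counts, and the *lon*-deletion libraries 30081576 and 33216852. Protein-coding genes took 60.7% and 61.1% of the counts in wild type and 58.2% and 55.6% in the deletion.

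The *lon* transcript (CCNA_02037) was examined first as a check of the genotype labels. It fell from 607 ± 59 CPM in wild type to 149 ± 8.5 CPM in the deletion (SD, n = 2 each), a log2 fold change of -2.02 (SE 0.11, edgeR adjusted p = 0.000133). Its fall was the largest of any gene. Reads were thus still assigned to *lon* in the deletion libraries, at a density of 62.2 RPKM. This lies above the floors of 22.0 and 20.03 RPKM described below for these libraries. The source of these reads was not tested. The adjacent gene CCNA_02036 rose from 201 ± 41 to 770 ± 68 CPM, a log2 fold change of 1.94 (SE 0.16). The neighbouring noncoding RNA gene CCNA_R0047 rose by 1.32 (SE 0.17). On the other side, *clpX* and *clpP*, which encode the ATPase and the peptidase of the ClpXP protease, rose by 0.45 (SE 0.12) and 0.87 (SE 0.08). CCNA_02040, between *clpX* and *clpP*, had a log2 fold change of -0.01 (SE 0.07). The rise of *clpX* was lost without *lon* deletion replicate 2 (0.39, edgeR adjusted p = 0.112), on library totals (0.08, edgeR adjusted p = 0.585) and after floor subtraction (0.03).

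Many genes were called as changed between the genotypes. Of 4084 genes, 1231 were higher and 1348 lower in the deletion, while 1504 did not pass. The calls came from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. In simulated data the floors of the real libraries were added to signal that was unchanged for all but 200 genes. There the same test called 624 unchanged genes higher and 856 lower. The counts of changed genes may therefore include many calls that the floor alone would give. A change of at least 2-fold was found for 154 genes that rose and 200 that fell, against 72 and 592 on library totals and 174 and 81 after the floor subtraction described below. The largest rises were those of 3 genes without a symbol: CCNA_03327 rose 12.5-fold from 62.2 ± 0.66 to 776 ± 144 CPM, CCNA_03906 rose 11.2-fold and CCNA_03169 had a log2 fold change of 3.46. Among genes with a symbol, *rpoH*, the heat-shock sigma factor gene, rose most (4.57-fold). It was followed by *terB*, named for tellurite resistance (3.47-fold), and the antitoxin gene *parD1* (2.97-fold). The other 7 of the 10 largest rises were *hdaA*, *higB*, *nstA*, *sidA*, *recA*, *socB* and *trx1*, at log2 fold changes from 1.51 to 1.31. Counts for *terB* and *hdaA* are uncertain because each overlaps a neighbouring gene.

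**Figure D1:**
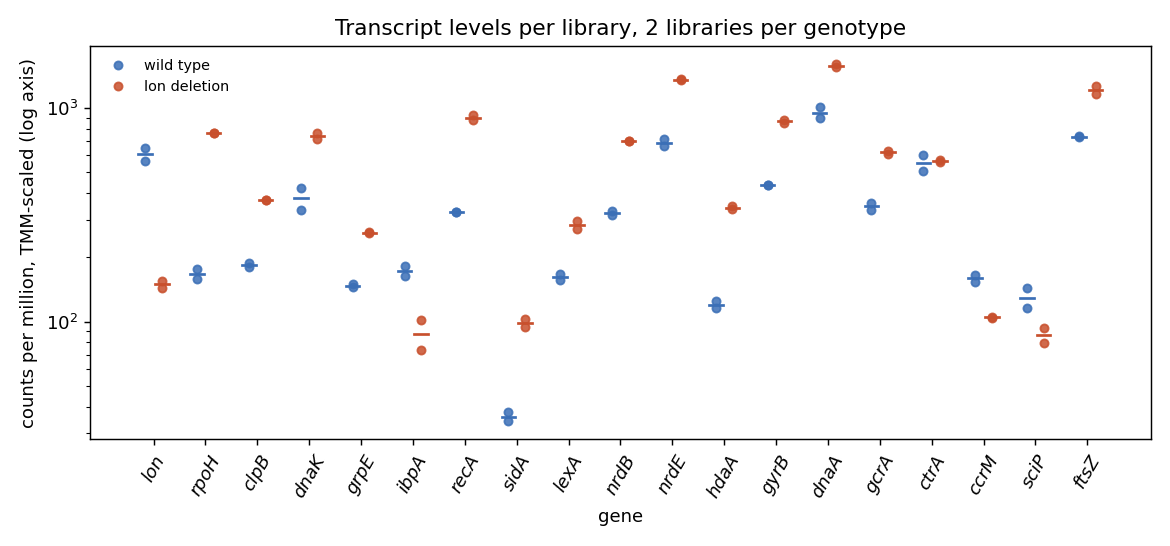
TMM-scaled CPM (log axis) of 19 named genes in each library; points are the 2 libraries of each genotype and bars their mean. *lon* falls from 607 to 149 CPM, *rpoH* rises from 167 to 765 CPM, and the *ctrA* libraries of the genotypes overlap.

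The number of genes called lower depended on scaling and on weakly covered genes. TMM scaling gave 47.7% of changed genes as higher. Upper-quartile scaling gave 32.7% (823 higher, 1697 lower) with the median gene at -0.14. Library totals gave 14.6% (394 higher, 2311 lower) with the median gene at -0.37. Without *lon* deletion replicate 2, 812 genes were higher and 1008 lower. The log2 fold change rose with read density, from a median of -0.90 in the lowest density decile of protein-coding genes to 0.47 in the highest. Spearman's rho was 0.79 across 3473 genes, which are not independent replicates. The 2nd percentile of read density, called the floor here, was 41.6 and 41.1 RPKM in wild type and 22.0 and 20.03 in the deletion. If present on every gene, it would hold 28.5% and 28.2% of protein-coding reads in wild type, and 12.6% and 11.2% in the deletion. Named genes that rose, and not only those that fell, could have wild-type densities near the floor. Such rises included *terB* (52.1 RPKM), *bapE* (57.7), *clpB* (71.5), *nrdJ* (75.0), *imuA* (76.7) and *clpA* (80.2). After subtraction of this floor, an alternative chosen after seeing the data, 558 genes were higher and 455 lower among 2965 with enough reads left. Of these, 534 higher and 365 lower genes had the same call before subtraction, and 0 had the opposite call. The 1119 genes left out included 860 that were called lower on the reads as counted and 26 called higher. Among weak genes the filter kept rises more readily than falls, because it used the mean of all 4 libraries. Counts and list calls after subtraction depend on this.

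**Figure D2:**
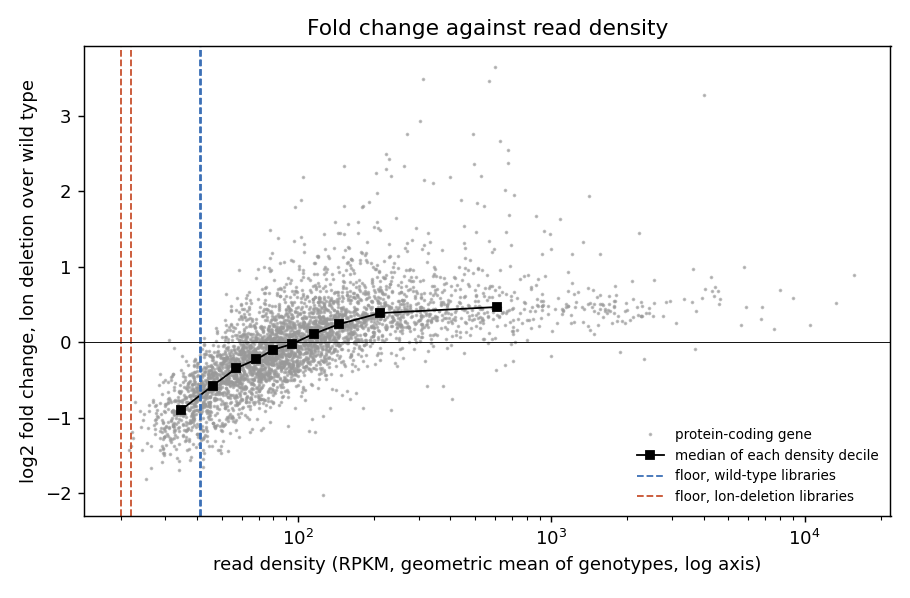
Log2 fold change of each protein-coding gene against its read density (geometric mean of the genotypes, RPKM, log axis), with medians of the density deciles and the floor of each library as dashed lines. The decile medians climb from -0.90 to 0.47, and the wild-type floors (41.6 and 41.1) lie above the *lon*-deletion floors (22.0 and 20.03).

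The proteotoxic stress genes were examined next. Of 6 heat-shock genes matched by symbol, 5 rose and 1 fell (5 and 1 also when adjusted over the list alone). This list passed upward (camera adjusted p = 0.00915, and adjusted p = 0.521 with an estimated correlation). *rpoH* rose from 167 ± 14 to 765 ± 0.49 CPM, with a log2 fold change of 2.19 (SE 0.10). The disaggregase gene *clpB* rose 2.01-fold. The chaperone gene *dnaK* rose by 0.96 (SE 0.13), and *grpE* and *dnaJ*, encoding the partners of DnaK, by 0.83 and 0.66. *ibpA*, a small heat-shock protein gene, was the member that fell, by 0.98 (SE 0.16). CCNA_00721 and CCNA_00722, which the plan named for this list by locus tag, were not in the list as tested. They rose by 1.67 and 1.95, more than the ratio of the floors between genotypes (edgeR glmTreat adjusted p = 0.0347 and 0.0123). Of 9 genes of ATP-dependent proteases and their adaptors, 7 rose, *lon* fell and 1 did not pass. *clpA*, the ATPase of the ClpAP protease, rose 2.20-fold, and *clpS*, its adaptor, rose 2.43-fold. The protease list missed the threshold (camera adjusted p = 0.0724) but passed with limma-voom (0.0321). The list holds the deleted gene itself. Without *lon*, 7 of 8 rose and 0 fell (camera adjusted p = 0.00692, and adjusted p = 0.429 with an estimated correlation). After floor subtraction 4 of those 8 rose (camera adjusted p = 0.0407, and adjusted p = 0.446 with an estimated correlation). After floor subtraction the heat-shock list kept its call (camera adjusted p = 0.0465, and adjusted p = 0.454 with an estimated correlation), with *rpoH* at 2.01, *clpB* at 1.51, *dnaK* at 0.73 and *ibpA* at -1.52.

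Nucleotide supply and DNA replication genes were examined because the series title names nucleotide metabolism. All 5 genes matched by symbol to the list of deoxyribonucleotide supply rose (5 also when adjusted over the list alone, camera adjusted p = 0.0381, and adjusted p = 0.521 with an estimated correlation). *nrdB*, encoding a ribonucleotide reductase subunit, rose from 322 ± 8.1 to 701 ± 0.57 CPM, a log2 fold change of 1.12 (SE 0.09). *nrdE*, another ribonucleotide reductase gene by its symbol, was not in the list and rose 1.97-fold. The glutaredoxin gene *grx1* rose by 0.80, the adenylate kinase gene *adk* by 0.61, *gmk* by 0.35 and *nrdJ*, encoding a second class of ribonucleotide reductase, by 0.34. The list missed the threshold without *lon* deletion replicate 1 (camera adjusted p = 0.0593) and without replicate 2 (0.0606), with medians relative to all genes of 0.68 and 0.55 against 0.61 with all libraries. After floor subtraction 3 of the 5 rose (camera adjusted p = 0.0475, and adjusted p = 0.454 with an estimated correlation). The list missed the threshold with the floor at the 5th percentile (median 0.72, camera adjusted p = 0.0522) or within arcs (median 0.43, 0.0577). At the 2nd percentile *adk* (0.14, limma adjusted p = 0.439) and *gmk* (0.24, 0.258) did not pass. Upper-quartile scaling gave 3 of 5 as higher and library totals 2, with *adk* at 0.23 (edgeR adjusted p = 0.107). *nrdJ* and *gmk* were not called without *lon* deletion replicate 2 (0.36 and 0.32), and *nrdJ* not without replicate 1 (0.31). On library totals *nrdJ* and *gmk* had log2 fold changes of -0.03 and -0.02. *purH*, the only purine or pyrimidine synthesis gene identified, fell by 0.24.

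Of 13 genes of the DNA replication list, 9 rose and 1 fell (9 and 1 also when adjusted over the list alone; camera adjusted p = 0.00667, and adjusted p = 0.521 with an estimated correlation). *hdaA*, whose product inactivates the initiator DnaA, rose 2.85-fold, the gyrase gene *gyrB* rose 1.98-fold, and *dnaE*, encoding the replicative polymerase, rose 1.76-fold. 4 members matched by symbol were *parE* toxin genes, and without them 6 of 9 rose and 1 fell, with a median of 0.65 (camera adjusted p = 0.0381, and adjusted p = 0.521 with an estimated correlation). After floor subtraction 8 of the 11 genes kept rose and 0 fell (camera adjusted p = 0.00128, and adjusted p = 0.454 with an estimated correlation). Without the *parE* genes, 5 of the 7 kept rose (camera adjusted p = 0.0104, not run with an estimated correlation). Of 20 SOS and DNA repair genes, 10 rose and 6 fell (11 and 6 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0989). *recA*, which triggers the SOS response, rose from 327 ± 0.71 to 899 ± 36 CPM, a log2 fold change of 1.46 (SE 0.09). *sidA*, an SOS-induced inhibitor of division, rose by 1.46 (SE 0.09) and *lexA*, the SOS repressor gene, by 0.81 (SE 0.09). The recombination genes *addA* and *addB* fell by 0.87 each, at densities near the floor. The wild-type densities of *bapE* and *imuA*, which rose, were near it too. After floor subtraction the SOS list passed upward (10 of 15 rose, 2 fell, camera adjusted p = 0.0159, and adjusted p = 0.454 with an estimated correlation), with *bapE* at 1.68 and *imuA* at 1.03, while the mismatch repair gene *mutS* and the alkylation repair gene *alkB* stood at -0.61 and -0.65. The subtraction left out 5 members near the floor, *imuB* and 4 that had been called lower, *addA*, *addB*, *dinB* and *dnaE2*. The 15 genes left also passed with limma-trend without subtraction (camera adjusted p = 0.0480). On library totals 5 of the 20 were higher and 7 lower, with a median of -0.008.

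Of 19 measured toxin-antitoxin genes, 14 rose and 1 fell (14 and 1 also when adjusted over the list alone), and the list had the smallest p of all (camera adjusted p = 2.2e-06, and adjusted p = 0.521 with an estimated correlation). The toxin gene *higB* rose 2.85-fold and its antitoxin gene *higA* 2.38-fold. *parD1* rose 2.97-fold and its partner *parE1* 2.07-fold, while *socB*, whose product binds the replication clamp, rose 2.53-fold together with *socA* (log2 fold change 1.24). *brnT* rose 2.07-fold, and *relE1* was the member that fell, by 0.51 (SE 0.09). After floor subtraction 12 rose and 1 fell (camera adjusted p = 0.000355, and adjusted p = 0.454 with an estimated correlation).

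Cell cycle regulators moved in both directions. The transcript of *dnaA*, encoding the replication initiator and Lon substrate, rose from 952 ± 82 to 1580 ± 43 CPM (0.73, SE 0.12), and that of *gcrA*, encoding an S-phase transcription factor, rose by 0.84 (SE 0.09). The DNA methyltransferase gene *ccrM* fell by 0.61 (SE 0.08) and *sciP*, encoding an inhibitor of CtrA activity, fell by 0.59 (SE 0.13). The products of both are reported Lon substrates, as is that of *staR*, which rose by 0.24 (SE 0.08). *ctrA*, the master regulator gene, had a log2 fold change of 0.03 (SE 0.11, edgeR adjusted p = 0.828). After floor subtraction *ccrM* and *sciP* stood at -0.99 and -1.05, *gcrA* at 0.40 and *ctrA* at -0.43 (limma adjusted p = 0.0303). *dnaA* then missed the threshold (0.29, limma adjusted p = 0.0853), and *staR* stood at -0.06. *staR* also missed the threshold without wild type replicate 1 (0.20), *lon* deletion replicate 1 (0.19) or *lon* deletion replicate 2 (0.28), at fold changes close to 0.24. Of 30 regulators, 12 rose and 6 fell (12 and 6 also adjusted over the list alone), and the list did not pass (camera adjusted p = 0.139). Upper-quartile scaling gave 9 higher and 10 lower, library totals 7 and 13, and floor subtraction 5 and 7, with a median of -0.09.

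Of 12 genes reported as activated by CcrM or GcrA, 8 rose and 1, *perP*, fell (8 and 1 also when adjusted over the list alone; camera adjusted p = 0.00915, and adjusted p = 0.541 with an estimated correlation). *nstA*, a regulator of topoisomerase IV, rose 2.79-fold, and the division genes *ftsZ*, *ftsN* and *mipZ* rose by 0.73, 0.69 and 0.69. The fall of *perP* (-0.27) missed the threshold without wild type replicate 1 (-0.24), *lon* deletion replicate 1 (-0.21) or *lon* deletion replicate 2 (-0.36). After floor subtraction *perP* was at -0.68 (limma adjusted p = 0.0057). This list lost its call after floor subtraction (camera adjusted p = 0.102), and *ftsZ* then missed the threshold (0.31, limma adjusted p = 0.0564). Of 26 cell division genes, 12 rose and 3 fell (12 and 3 also adjusted over the list alone). The camera adjusted p was 0.0975, 0.0273 with limma-voom and 0.541 with an estimated correlation. Library totals gave 4 higher and 10 lower, and floor subtraction 5 and 4, with a median of 0.03.

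Motility and attachment genes were examined by list. Of 45 flagellar genes, 31 fell, 3 rose and 11 did not pass (32 fell and 4 rose when adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.000289, and adjusted p = 0.521 with an estimated correlation). *fliO*, of the flagellar export apparatus, fell from 66.7 ± 2.1 to 39.6 ± 0.32 CPM, a log2 fold change of -0.75 (SE 0.08). *flgI*, *fliI* and *flaN* fell by 1.08, 1.08 and 0.82, at densities near the floor. Of 31 pilus and holdfast genes, 21 fell, 1 rose and 9 did not pass (21 and 1 also adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.545 with an estimated correlation). Examples were *cpaE* (-0.64) and *hfsG* (-0.83). The pilus and holdfast list missed the threshold without *lon* deletion replicate 1. Its median relative to all genes was then -0.33, against a median of -0.36 with all libraries. After floor subtraction 19 of 33 flagellar genes fell and 1 rose, and 20 of 27 pilus and holdfast genes fell and 0 rose (camera adjusted p = 1.3e-07 for each, and adjusted p = 0.454 for each with an estimated correlation). The correlation was then estimated at 0.007 for the flagellar list and 0.234 for the pilus and holdfast list. Against the preset 0.01, the p at the preset is thus less cautious for the pilus and holdfast list. Of 10 swarmer-cell markers, 3 fell and 1 rose (3 and 1 also adjusted over the list alone; camera adjusted p = 0.681). After subtraction 4 fell (camera adjusted p = 0.0147, and adjusted p = 0.491 with an estimated correlation), including the holdfast inhibitor gene *hfiA* (-0.84), the hook gene *flgE* (-1.13) and the flagellin gene *fljK* (-0.59).

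The largest falls after *lon* lay among weakly covered genes. CCNA_02862, which overlaps a neighbour, fell 3.52-fold and CCNA_00580 fell 3.23-fold. 6 of the 9 largest falls with a symbol other than *lon* lay in a single stretch of neighbouring genes from *nrtB* to *nasC*, so they are not separate observations: *nasE* (-1.66), *nasC* (-1.48), *narK* (-1.41), *nrtB* (-1.31), *nasT* (-1.26) and *nirB* (-1.24). The other 3 were *cheWII* (-1.47), *cheAII* (-1.31) and *cheBII* (-1.24), which also lie close together. Their wild-type densities were 52.4 to 83.1 RPKM, and all 9 were left out of the subtraction because under 50% of their reads remained. The ratio of the floors alone corresponds to a log2 fold change of -0.98. A test against that ratio, chosen after seeing the data, found 76 genes that rose by more than this size and 30 besides *lon* that fell by more. Among the falls were *nasE*, *nasC*, *narK*, CCNA_02862 and CCNA_00580 (edgeR adjusted p = 0.0230, 0.0138, 0.0472, 0.00178 and 0.0217). Of 15 chemotaxis genes, 6 fell and 0 rose (6 and 0 also adjusted over the list alone; camera adjusted p = 0.179). That list passed without wild type replicate 1, although its median, relative to all genes, moved from -0.15 to -0.036. With all libraries and an estimated correlation its camera adjusted p was 0.545. After floor subtraction 0 of the 9 chemotaxis genes kept passed.

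All 26 ribosomal protein genes rose (26 also when adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.00398, and adjusted p = 0.541 with an estimated correlation) and 0.63 for *rplS*. Of 31 genes of ATP synthase and respiration, 16 rose, 0 fell and 15 did not pass (16 and 0 also adjusted over the list alone; camera adjusted p = 0.0422, and adjusted p = 0.599 with an estimated correlation), among them *nuoA* (0.71) and *nuoH* (0.54). After floor subtraction 0 of 26 ribosomal protein genes passed, with a median of -0.003, and 1 of 28 respiration genes passed, with a median of -0.02. On library totals 1 of 26 ribosomal protein genes was higher with a median of 0.10, and the median of the respiration genes was -0.003. The respiration list also missed the threshold without wild type replicate 2 (median relative to all genes 0.31, camera adjusted p = 0.0626) and without *lon* deletion replicate 2 (0.35, 0.790), against a median of 0.40 with all libraries.

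Over the 22 lists tested, 7 passed upward and 2 downward on the reads as counted, and 5 upward and 3 downward after floor subtraction. With an estimated correlation 0 lists passed, with a lowest adjusted p of 0.521 as counted and 0.454 after subtraction. Fry passed 17 lists. On library totals, where the median gene was at -0.37, the medians of the SOS, cell cycle, cell division, respiration, general stress, peptidoglycan and capsule lists turned below 0.

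**Figure D3:**
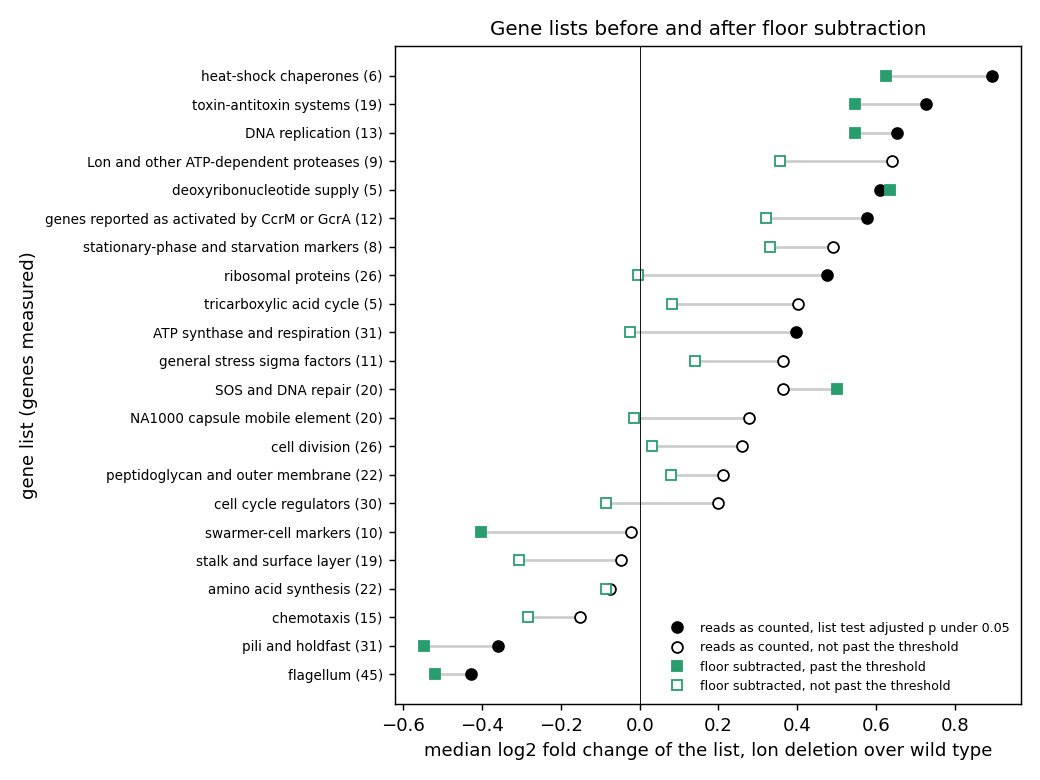
Median log2 fold change of each of the 22 tested gene lists (genes measured in brackets) on the reads as counted (circles) and after floor subtraction (squares); filled symbols passed the list test. Heat-shock, deoxyribonucleotide, replication and toxin-antitoxin lists pass upward and flagellum and pilus lists downward in both, while the ribosomal protein median moves from 0.48 to -0.003.

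Because Lon degrades DnaA, fold changes were compared with gene distance from the replication origin. Genes farther from the origin had slightly higher values, with a slope of 0.10 log2 units per 1000 genes. The slope did not pass a two-sided permutation test by 4083 circular shifts of the gene order (p = 0.143). After floor subtraction the slope was 0.24 (permutation p = 0.197), and with floors taken within arcs it was 0.05 (permutation p = 0.509).

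**Figure D4:**
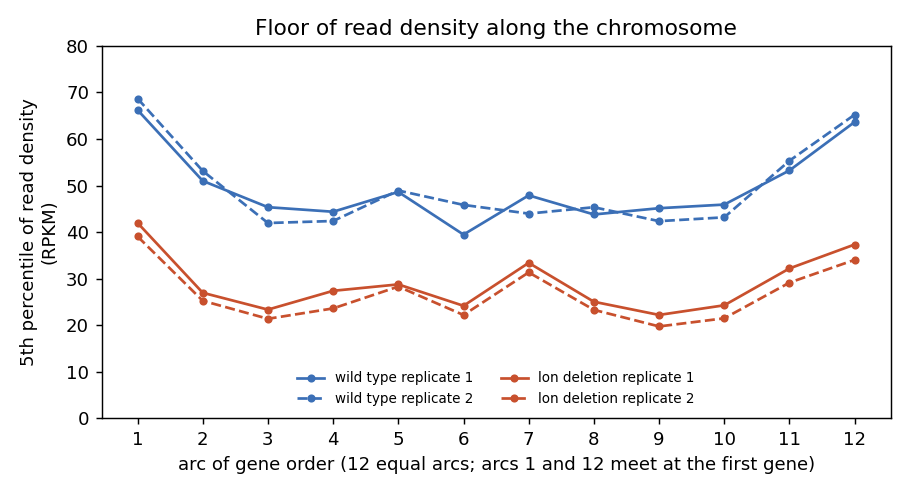
The 5th percentile of read density (RPKM) of protein-coding genes in 12 equal arcs of gene order, with 1 line per library. All 4 libraries have their highest values in arcs 1 and 12, which meet at the first gene, and both wild-type lines lie above both *lon*-deletion lines in every arc.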

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

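Floor subtraction, its settings, limma-trend on the genes it kept and the lists without *lon* or the *parE* genes were chosen after seeing the data; the other alternatives were planned. Neither low-count filter removed a gene, so these tests say nothing. Of 102 genes followed, 102 kept direction and call with RLE scaling, the likelihood-ratio and legacy tests, limma-voom and the replicate block, and 101 with the DESeq2 test. The genotypes share replicate numbers, but the sample titles do not say whether these pair the samples. The deviations of replicates of the same number correlated at 0.347 across genes, so a pairing is possible, and the main test leaves it out. With the replicate block 1427 genes were higher and 1448 lower, against 1231 and 1348 in the main test. Leaving out single libraries gave 812 to 1316 higher and 1008 to 1314 lower genes, 148 to 167 and 172 to 259 at 2-fold, 6 to 7 lists up and 1 to 3 down, and slopes of 0.09 to 0.11 log2 units per 1000 genes; this also leaves 1 library in a genotype, assumed to vary like the others. Of 2580 calls (with *lon*), 1791 kept direction and call without *lon* deletion replicate 2, with 0 changes of sign.

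Library totals gave 394 higher and 2311 lower genes, 72 and 592 at 2-fold, and turned *ctrA* (-0.34), *nrdJ* (-0.028), *staR* (-0.13) and *gmk* (-0.022), while 9 of the genes followed lost their calls: *clpX* (0.08), *adk* (0.23), *rplS* (0.26), *rpsQ* (0.11), *rplO* (0.13), *nuoH* (0.17), *nepR* (0.30), *dnaG* (0.03) and *ppk1* (0.16). This follows from its shift of all genes. Floor subtraction tests fewer genes and removes more reads from wild type. At the 2nd percentile it gave 558 higher and 455 lower (81 lower at 2-fold). At the 1st it gave 537 and 523 (103; 4 lists down), at the 5th 513 and 393 (69; 4 lists up, 4 down), and within arcs 464 and 273 (54; 4 down). Limma-trend without subtraction on the genes kept gave 704 and 782 (30; 4 down). The origin slope was 0.24, 0.23, 0.23 and 0.05 at the 2nd, 1st and 5th percentile and within arcs, and 0.16 with limma-trend, none passing (p from 0.167 to 0.509).

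In the order 2nd, 1st and 5th percentile and arcs, *ctrA* was at -0.43, -0.42, -0.47 and -0.48 and *staR* at -0.058, -0.062, -0.082 and -0.11. Ribosomal protein medians, relative to all genes, were -0.0097, 0.020, -0.040 and -0.041; the list test pointed down in each, against the sign of the 0.020. Respiration medians were below 0 in all 4 (-0.031, -0.0050, -0.053 and -0.047). Values turned at the 2nd and 5th percentile and within arcs for *rpsQ* (-0.0042, -0.039 and -0.049), at the 5th and within arcs for *clpX* (-0.0034 and -0.033), and within arcs for *rplO* (-0.0082). The deoxyribonucleotide list missed the threshold at the 5th percentile and within arcs. Lists that missed the threshold as counted but passed under some of these settings included chemotaxis (1st and 5th percentile), general stress (within arcs), amino acid synthesis (within arcs and with limma-trend) and stalk (limma-trend). With an estimated correlation 0 lists passed up and 0 down, as counted or after subtraction at the 2nd percentile; limma-voom passed 10 up, adding the protease (0.0321), cell division (0.0273) and stationary-phase lists (0.0407), and fry, which does not compare lists with other genes, passed 14 up. Apart from the few residual degrees of freedom under an estimated correlation, the cause of these was not tested. As counted, the estimates lay well above the preset 0.01 for the pilus and holdfast (0.27), ribosomal protein (0.28) and respiration lists (0.32). For other lists they lay below it, as for DNA replication (-0.08) and deoxyribonucleotide supply (-0.17). Counts were not thinned, so the effect of depth on the calls was not tested; every gene had at least 92 counts.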

Other observations

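The lipid A synthesis gene *lpxC* rose 2.40-fold and the penicillin-binding protein gene *pbpZ* fell 1.93-fold, while the peptidoglycan and outer membrane list had 9 higher and 2 lower of 22 genes (9 and 2 also adjusted over the list alone) and did not pass (camera adjusted p = 0.215). After floor subtraction 1 was higher and 1 lower, on library totals 1 and 10, and *pbpZ*, near the floor, was left out of the subtraction. Of 11 general stress sigma factor genes 6 rose and 2 fell (6 and 2 also adjusted over the list alone; camera adjusted p = 0.0654), led by *rpoH* and *sigU* (1.13, SE 0.12). That list passed without *lon* deletion replicate 2, with a median relative to all genes of 0.32 against a median of 0.36 with all libraries. With all libraries and an estimated correlation its camera adjusted p was 0.541. After floor subtraction 2 of 10 rose and 0 fell, and on library totals 2 were higher and 5 lower. Of 8 stationary-phase and starvation markers 6 rose and 1 fell (6 and 1 also adjusted over the list alone; camera adjusted p = 0.0654, and 0.0407 with limma-voom), and 4 of 8 rose after floor subtraction. *cspD*, of the cold-shock protein family, rose 2.34-fold, *sspB* 1.68-fold and the polyphosphate kinase gene *ppk1* 1.45-fold (not called on library totals). The catalase-peroxidase gene *katG* was the marker that fell, by 1.18 (SE 0.34), with densities of 231 and 101 RPKM in the wild-type libraries, and was at -0.46 without replicate 1. It was not called by DESeq2 (adjusted p = 0.0627) or after floor subtraction (-1.53, limma adjusted p = 0.0652, and 0.0641 to 0.0759 over the 4 floor settings).

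*glnA2*, encoding a glutamine synthetase, fell by 0.91 and *gltB*, encoding a glutamate synthase subunit, by 0.68, both near the floor, and 8 of 22 amino acid synthesis genes fell while 2 rose (8 and 2 also adjusted over the list alone; camera adjusted p = 0.347). After floor subtraction 4 of 17 fell and 0 rose. Upper-quartile scaling gave 2 of the 22 higher and 11 lower, and library totals 0 and 17. *phoB*, the phosphate response regulator gene, fell by 0.52 (SE 0.08), within a stalk and surface layer list of 8 lower and 4 higher of 19 genes (9 and 4 adjusted over the list alone; camera adjusted p = 0.635), and 8 lower and 2 higher after floor subtraction. Of 20 genes of the capsule mobile element 9 rose and 6 fell (9 and 6 also adjusted over the list alone; camera adjusted p = 0.635), and of 5 tricarboxylic acid cycle genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.215). After floor subtraction 1 capsule gene was higher and 1 lower of 13, and 0 tricarboxylic acid cycle genes passed, with a median of 0.08 although the list test pointed down. On library totals 0 of the latter passed, with a median of 0.03. For the 20 capsule genes, upper-quartile scaling gave 4 higher and 7 lower, and library totals 1 and 8. Of 4 oxidative stress genes 2 rose and 1 fell, and of 4 reported Lon substrates 2 rose and 2 fell; after floor subtraction 0 of 3 oxidative stress genes passed, and 0 of 4 Lon substrates rose and 2 fell.

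The tests of the following patterns were chosen after the results were seen, except that of density-matched permutations. Fold change rose with read density. A candidate explanation is a read background spread evenly over the genome and larger in the wild-type libraries. The wild-type floor, as a share of protein-coding reads, was at least 1.85 times the *lon*-deletion floor in each of 4 gene length classes, and on the genes kept rho went from 0.64 to 0.23 after subtraction. A change of weak and strong genes in opposite directions with the genotype cannot be told apart from it (rho 0.23 remaining), because the floor differs with genotype in all 4 libraries.

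The floor was also higher near the first gene of the chromosome, where replication starts. Its 5th percentile in the arcs there was 1.37 to 1.49 times that in the arcs halfway round, in all 4 libraries. Residual DNA may account for this, since growing cells hold more copies of origin-proximal genes. Weak transcription of the whole chromosome would give the same gradient (up to 1.49), and the reads as counted per gene, with no strand, keep the DNA and RNA sources open.

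A stretch of 50 neighbouring genes from *sixA* to CCNA_00609 held 43 that fell and 1 that rose. Chance clustering of weakly covered genes is argued against, since 9 of 1000 permutations within density deciles gave a window with as many falls, although neighbours in operons are not independent. The median stayed below 0 without either wild-type library, at -0.49 without replicate 2 and -0.94 without replicate 1. Median densities in the stretch were 69.6 and 92.2 RPKM in wild type and 46.3 and 49.1 in the deletion. With all libraries, the density deciles with means of 57.15 and 68.49 RPKM had median log2 fold changes of -0.34 and -0.23. How much of the fall rests on wild type replicate 2 was not tested against genes of like density. A read background that differs between the genotypes stays open: on the reads as counted the median (-0.71) did not reach the ratio of the floors in its arcs (-0.996), and 3 of the 50 fell past the genome-wide ratio. After floor subtraction the median of the members kept was -0.62 (27 genes, 13 fell, 0 rose), and -0.45 with floors taken within arcs (21 genes, 6 fell, 0 rose), but the window was chosen for its falls.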
